A study of Mus musculus with 6 samples.

How the data were processed

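RNA was measured in 6 aorta samples of angiotensin II-treated mice, 3 labelled wild type and 3 labelled Josd2 knockout. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected, and paired-end libraries were sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and genome build mm8, with no role or order. The counting tool, the annotation, the use of strand and any filter are not given in the sources used here. The gene coordinates in the deposited table were identical to those of GENCODE release M21, on GRCm38, for 92.5% of its gene identifiers, so coordinates are given as the table has them and no mm8 coordinates are used here.

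The table holds, per the file headers, counts and FPKM for 41064 genes in each library. The deposited FPKM values, fragments per kilobase and scaled to each library's total by the authors, include mitochondrial genes in that total, as the ratio of count to FPKM between libraries equals the ratio of their count totals. The deposited counts are whole numbers whose low values peak at 4, 8 and 12, with 1091 to 1137 genes per library at 4 counts against 792 to 867 at 3 and 472 to 519 at 5. Other values are common as well, as 26.2% to 27.7% of counts from 1 to 20 are divisible by 4. From these peaks they were treated as estimated counts written by the authors as whole numbers, about 4 per read pair, which no source states. They were rounded before testing, which changed none of them. How the authors made these estimated counts is not given in the sources used here.

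The test planned before the data were examined was limma on log2(FPKM + 1), unless the table also held counts. Since it does, the edgeR quasi-likelihood test replaced it as that plan states, and limma on FPKM became an alternative. Genes passed edgeR's filterByExpr, libraries were scaled with TMM, and p-values were adjusted by the Benjamini-Hochberg method over 20132 genes with a threshold of 0.05. The common biological coefficient of variation that edgeR fitted was 24.4% and the prior degrees of freedom 6.59. That single value does not describe abundant genes. In wild type the median coefficient of variation went from 34.8% at mean counts of 30 to 100 to 1.39% at 30000 to 100000. Fold changes are labelled knockout over wild type on the log2 scale. CPM are counts divided by the TMM-scaled library size, given as mean and SD of 3 libraries. No batch is stated in the labels.

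A fold against a group at 0 counts was computed against a floor of 3 read pairs, or 12 counts, per library, and genes with 1 to 3 read pairs in a group are given a ratio with its 95% counting interval. Both cover counting error only, as the reads carry no molecular identifiers. Total counts of 63612353 to 75886761 per library set that floor at 0.137 to 0.218 CPM.

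The 37 gene lists were tested with camera from limma at a preset correlation of 0.01 when at least 5 members were tested, with camera at an estimated correlation and fry beside it. Camera also tested GO and KEGG terms of 10 to 300 tested genes, taken from the deposited annotation. The mean log2 fold change of a list includes fitted values of genes at 0 counts.

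Genes were named by a rule fixed before the data were examined. It takes the 13 study genes, the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, a mean FPKM of at least 1 in the higher group, groups that do not overlap and a symbol that is not a predicted model, and up to 4 members of each named list or term with the smallest p. Of the genes that this rule names, 1 is not reported here. Chosen after values were seen were the ribosome and MHC class II terms, and the MHC class I term without its members. Hoxa4, Hoxc11, Hoxa13, Hoxb4, Nnt and Ighm were chosen in that way too. So were the lists for anterior, middle and posterior Hox genes, lung, kidney, seminal vesicle, thymocytes and lymphatic endothelium. Named genes were compared with other transcripts by BLAST+ 2.17.0 (at least 97% identity over 100 bases) and with overlapping exons.

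On simulated counts of 19230 tested genes, the edgeR steps recovered 52.9% of 68 known 1.5-fold, 92.4% of 66 2-fold and 97.0% of 66 4-fold changes, with 5 false calls, 3.01% of all calls. Changes were planted in few genes, only at higher mean counts and about evenly up and down, without a mitochondrial shift. These rates therefore do not carry over to low-count genes or to data with many changes. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Alternatives were DESeq2, its size factors in edgeR, library totals, no filter, filters on mean FPKM of 1 and 5, counts divided by 4, robust edgeR, limma on FPKM with several pseudocounts, scalings and variance models, the replicate number as a block, mitochondrial or other tissues' genes left out, and each library left out in turn.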

Results

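Aortas of mice given angiotensin II, a vasoconstrictor peptide used to provoke vascular remodelling, were profiled by RNA sequencing. Of the 6 libraries, 3 came from wild type mice and 3 from mice labelled as knockouts of Josd2, a deubiquitinase of the Josephin family. Angiotensin II was given to both groups and untreated libraries were not analysed here, so each difference is one between the labelled groups under treatment. Summed counts per library lay between 63612353 and 75886761 in the deposited unit. It was read as about 4 counts per read pair, from peaks of low counts at 4, 8 and 12. The numbers of read pairs, counting intervals and floors below rest on that reading. The spread between libraries was wider than that reading gives, so the counting intervals are too narrow. Among 41064 genes in the table, 20132 passed the filter on low counts. Levels are given as CPM, counts scaled with TMM factors to a common library size, as mean ± SD of n = 3 libraries, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

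Josd2, the targeted gene, was still detected in all 3 libraries labelled knockout. It lies on mouse chromosome 7 from 44467980 to 44471662 on the plus strand, coordinates as the deposited table gives them, which match mouse build GRCm38 gene models. Its level was 30.1 ± 0.837 CPM in wild type and 20.98 ± 0.947 CPM in the libraries labelled knockout (log2 fold change -0.52, SE 0.07, edgeR adjusted p = 0.000244). The labelled knockouts thus kept 69.8% of the wild type level, with 1742, 1737 and 1780 counts in single libraries against 1649, 1762 and 1890. On the deposited FPKM scale they kept 92.8%, at 7.76 ± 0.356 against 8.36 ± 0.224, and scaled by library totals the difference no longer passed edgeR's test (log2 fold change -0.11, adjusted p = 0.231, between 0.0981 and 0.231 over that scaling and the limma fits on FPKM as deposited). The table gives no counts per exon, so a deletion of part of the gene was neither seen nor ruled out. Because the transcript was retained, these samples are called libraries labelled knockout throughout, and every direction rests on that label. Of the Josephin family, Atxn3, the ataxin-3 deubiquitinase, was higher (0.46, SE 0.09, edgeR adjusted p = 0.0028), while Josd1 did not pass (-0.06, SE 0.07, edgeR adjusted p = 0.588). With library totals Josd1 passed upward, at 0.35 (edgeR adjusted p = 0.00134).

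The libraries split by group on the first principal component, which held 40.6% of the variance. Pairwise correlations of log2 CPM were 0.953 to 0.972 within groups and 0.939 to 0.945 between them. Mitochondrially encoded transcripts took 36.2% of all counts in wild type (SD 0.0282 percentage points) and 23.9% in the libraries labelled knockout (SD 0.0274 percentage points, n = 3 each), and 47.0% against 31.0% with 11 nuclear copies of mitochondrial sequence included. All 13 tested mitochondrial mRNAs fell, with a median log2 fold change of -1.02. Limma camera gave an adjusted p of 8.64e-143 at its preset correlation and 0.000375 at an estimated one. That call was lost after quantile normalisation of FPKM (limma camera adjusted p = 0.929). Such normalisation gives genes of equal rank in each library the same value by construction. Among these mRNAs, mt-Co1, a cytochrome oxidase subunit, was 2.0-fold lower and mt-Cytb stood at -1.02. The complex I subunits mt-Nd2 and mt-Nd4 stood at -1.08 and -1.03. Nuclear copies share 100% of the mt-Co1 transcript and 63.6% of mt-Nd4. Scaled by library totals, the median gene lies 0.41 log2 higher in the labelled knockouts than on the TMM scale. With mitochondrial genes and copies left out, that shift is 0.03. All changes are given relative to the TMM scale.

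Between the groups 4981 genes changed, 2658 higher and 2323 lower in the libraries labelled knockout, and 1200 of these changed at least 2-fold (518 higher, 682 lower). With library totals in place of TMM, edgeR called 10193 genes, 92.5% of them higher against 53.4% in the main test. Of the changed genes, 4955 had groups that did not overlap, as did 41.1% of all tested genes, where chance gives 10%. The design text speaks of 3 mice per group, but no label ties a library to an animal, and genes with mean counts above 10000 had a median coefficient of variation of 1.86% in wild type and 1.78% in the labelled knockouts. Variance over mean, taken from the median gene, was 9.25 to 12.2 in wild type and 8.32 to 9.74 in the labelled knockouts. These ranges cover bins of mean count from 30 to 100000, without a steady rise. A spread between animals in proportion to the level would raise it with the count. For typical genes these values argue against a sizeable spread of that kind. The p-values therefore measure only the spread between these samples, which may be technical. If it is technical, they do not separate genotype from differences between animals, pools or dissections.

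Among the 10 genes with the largest increases, 8 were immunoglobulin variable segments, which encode parts of antibodies made by B cells and plasma cells. At 0 counts in all wild type libraries, Igkv14-130 was at least 4.25-fold higher, Ighv14-1 at least 3.44-fold, Ighv8-6 at least 2.10-fold and Ighv1-59 at least 1.84-fold, against a floor of 3 read pairs (12 counts) per library. Their rank rests on fitted folds, which are no bound, and these bounds lie below the 16.8-fold increase of Coch. Ighv14-4 had 1 read pair in wild type and 33 in the labelled knockouts (ratio 23.2, 95% counting interval 3.88 to 944), Ighv1-52 had 2 and 54 (ratio 19.0, 5.01 to 161), and Ighv14-3 had 3 and 64 (ratio 15, 4.91 to 74.6). Igkv6-25 rose from 0.0907 ± 0.102 to 1.41 ± 0.199 CPM. Similar segments share at least 83.9% of the transcripts of Ighv14-1, Ighv14-4, Ighv1-52 and Ighv8-6, so their counts are uncertain between family members. The calls of Ighv14-4, without any 1 of the labelled knockout libraries, and of Ighv1-52, without labelled knockout 2, were lost. Coch, which encodes the secreted protein cochlin, rose from 0.478 ± 0.290 to 8.01 ± 1.002 CPM (log2 fold change 4.07, SE 0.35), and Clca3a1, of the calcium-activated chloride channel regulators, rose from 2.64 ± 0.400 to 32.8 ± 1.52 CPM (3.63, SE 0.12). Of the Clca3a1 transcript, 39.9% matches another gene.

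The 10 largest decreases included Hoxa11, a posterior homeobox gene, which fell from 3.42 ± 0.309 CPM to 0 counts, at least 22.9-fold, with 34.98% of its exon bases overlapped by an antisense gene and no strand setting stated. Hoxa11 and Svs4 were ranked by fitted folds as well. Transcripts of other organs stood beside Hoxa11. The seminal vesicle protein Svs4 fell at least 8.35-fold to 0 counts, Svs5 had 43 read pairs in wild type and 2 in the labelled knockouts (ratio 30.6, 95% counting interval 7.97 to 261), and the lung surfactant gene Sftpc fell from 7.51 ± 1.20 to 0.125 ± 0.108 CPM. The kidney water channel Aqp2 fell from 16.6 ± 0.662 to 0.358 ± 0.138 CPM and the renin gene Ren1 from 2.502 ± 0.492 to 0.0731 ± 0.0672 CPM. Spon2, a secreted matrix protein, was 55.5-fold lower (30.3 ± 1.40 against 0.548 ± 0.229 CPM), the vasopressin receptor Avpr1a 30.5-fold lower and the platelet chemokine Ppbp 30.2-fold lower. The mitochondrial glycine tRNA mt-Tg had 215 read pairs in wild type and 3 in the labelled knockouts (ratio 102, 34.4 to 498). Leaving out the genes of lung, kidney, seminal vesicle, thymocyte and lymphatic lists and all immunoglobulin genes, edgeR called 4925 genes. As 19989 of 20132 tested genes remained, that count could hardly change. It cannot show what other tissue adds to the genes that remain.

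**Figure D1:**
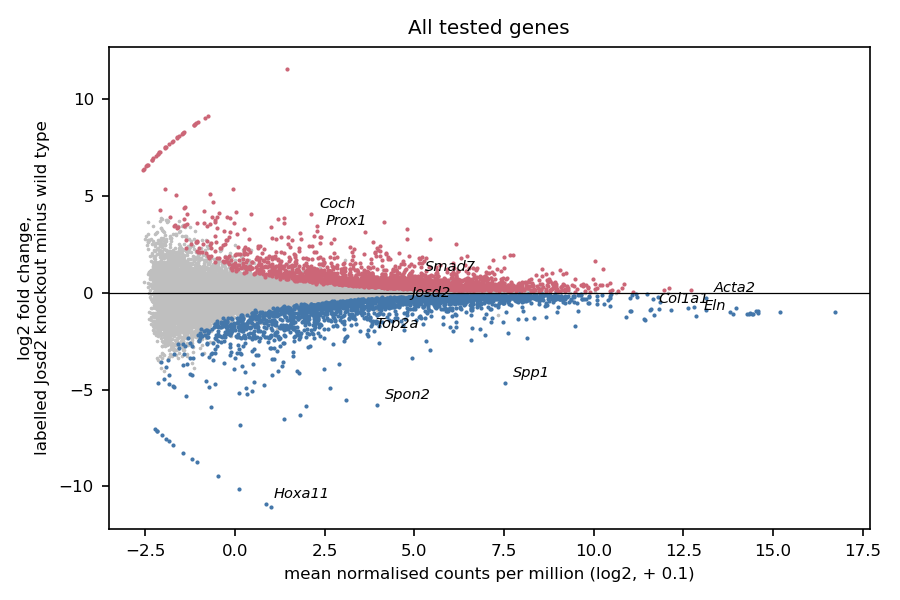
Log2 fold change between the libraries labelled knockout and wild type (n = 3 each) against the log2 of mean CPM plus 0.1, 1 point per tested gene. The 2658 genes that rose are red, the 2323 that fell are blue and the rest are grey, and the diagonal rows of points at both edges are genes at 0 counts in a whole group, whose fitted fold change is no bound.

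A total of 37 gene lists and the rule for naming genes were fixed before the data were examined, and 35 lists had enough tested members for a set test. Camera called 18 of them, 3 higher and 15 lower, and 12 of these calls held with an estimated correlation, those of TGF-beta response, matrix, matrix enzymes, modulated smooth muscle, endothelium, macrophages, inflammatory mediators, cell cycle, immediate early genes, mitochondrial transcripts, white fat and clock. With that correlation their limma camera adjusted p ran from 0.000375, for mitochondrial transcripts, to 0.034, for white fat. The smaller values printed for these lists below rest on the preset correlation. Fry, which tests whether a list's genes move on balance in a direction without comparing them with other genes, passed 26 lists, and its mixed test for changes in either direction passed 35. More members were lower than higher in 19 of the 37 lists and the reverse held in 12. With library totals these were 6 and 29, and 11 of the 19 turned to more higher than lower.

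The series title names SMAD7, an inhibitor of TGF-beta signalling, in vascular remodelling, and 13 study genes follow from that title. Of these, 9 changed (3 higher, 6 lower), and 10 did when adjusted over the list alone. Smad7 itself rose from 24.4 ± 1.12 to 42.6 ± 2.04 CPM, 1.75-fold (log2 fold change 0.80, SE 0.07, edgeR adjusted p = 5.61e-06). Tgfb1, the ligand, fell by 0.51 on the log2 scale (SE 0.07, edgeR adjusted p = 0.000283), and the receptor gene Tgfbr2 rose by 0.31 (SE 0.04). Smad3, a signal transducer of the pathway, fell by 0.31 (SE 0.08, edgeR adjusted p = 0.0172). Smad2 (0.03, SE 0.10), Smad4 (-0.10, SE 0.06), Tgfbr1 (-0.13, SE 0.05) and the angiotensin receptor gene Agtr1a (0.54, SE 0.33) did not pass. Without wild type 3, labelled knockout 1 or labelled knockout 2, Smad3 lost its call (edgeR adjusted p of 0.0548 to 0.0827), while Tgfbr1 gained one downward without wild type 2, in DESeq2, at a mean FPKM of at least 1 and on counts divided by 4. Scaled by library totals, Smad3 changed sign (0.10), and it and Tgfb1 lost their calls. Smad4 (0.31) and Tgfbr1 (0.28) changed sign and passed upward with that scaling (edgeR adjusted p = 0.000856 and 0.000747). Smad2 (0.44) and Agtr1a (0.95) also passed upward (edgeR adjusted p = 0.00423 and 0.0329).

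**Figure D2:**
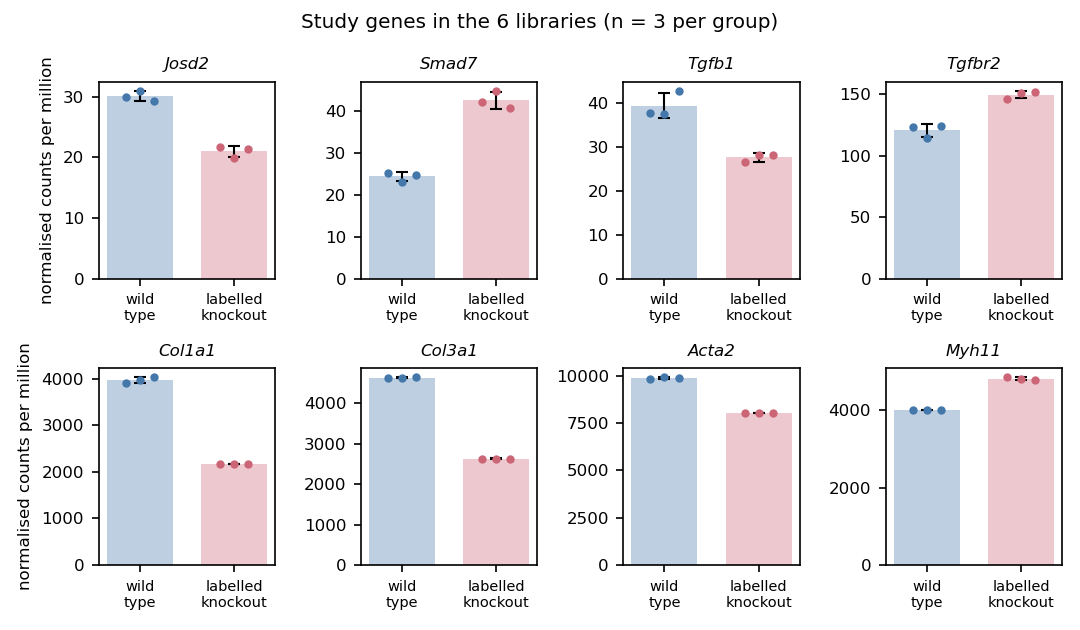
Normalised counts (CPM) of 8 study genes in wild type and in libraries labelled knockout, with bars for means, points for the 3 libraries of each group and error bars for the SD. Josd2 stayed at 20.98 against 30.1, Smad7 was higher at 42.6 against 24.4, and Acta2, at 8037 against 9871, is lower on this scale but changes sign with library totals.

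Within a list of 27 components of TGF-beta signalling, 14 were higher, 4 lower and 9 did not pass (15 and 5 adjusted over the list alone). Those with the smallest p were Thbs1 at -2.33, an activator of latent TGF-beta, the latent TGF-beta binding proteins Ltbp4 at 1.20 and Ltbp2 at 0.54, and the ligand gene Tgfb3 at -0.53. As a set they did not pass (limma camera adjusted p = 0.0689), but did, upward, in 9 of 29 alternatives (adjusted p of 7.37e-07 to 0.0498). These were library totals (median 0.61, 23 of 27 higher), library totals with mitochondrial genes and copies left out, no filter, median-of-ratios factors and quantile normalisation on FPKM, fry, members of several lists left out, and the fits without wild type 1 or without labelled knockout 1. Of 27 genes that TGF-beta induces, 16 fell, 8 rose and 3 did not pass, the same counts as adjusted over the list alone, with a median of -0.26 (limma camera adjusted p = 1.45e-14). Library totals put that median at 0.15 with 15 higher and 9 lower, and the call was lost (limma camera adjusted p = 0.313). It was lost too after quantile normalisation of FPKM (limma camera adjusted p = 0.109), and with members of several lists left out, where 11 genes were tested (limma camera adjusted p = 0.441). The 4 members with the smallest p, Eln, Fn1, Col3a1 and Col1a1, fell and are also on the matrix list below. Among the 8 that rose were Id1 at 1.53 and Smad7 at 0.80.

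Structural matrix genes fell in the libraries labelled knockout. Of 39 collagens and other matrix genes, 28 fell, 9 rose and 2 did not pass (28 and 10 adjusted over the list alone), with a median log2 fold change of -0.32 (limma camera adjusted p = 1.58e-36). Library totals turn that median to 0.09 with 18 lower and 20 higher, while the list's call stays downward relative to other genes (limma camera adjusted p = 0.000175). Eln, which encodes elastin, fell from 10222 ± 64.1 to 4440 ± 24.5 CPM, 2.30-fold. The fibronectin gene Fn1 fell 1.68-fold, Col3a1 from 4625 ± 7.12 to 2624 ± 7.67 CPM, and Col1a1 from 3968 ± 61.1 to 2170 ± 7.32 CPM. The matricellular Thbs1 fell 5.03-fold. Of 31 enzymes that crosslink or remodel matrix and their inhibitors, 19 fell, 4 rose and 8 did not pass (20 and 5 adjusted over the list alone), with a median of -0.24 (limma camera adjusted p = 6.99e-11). Library totals turn that median to 0.17 with 14 higher and 8 lower, without a call (limma camera adjusted p = 0.0571). The crosslinking enzyme gene Lox fell 2.39-fold, the protease inhibitor gene Timp1 3.49-fold and the gelatinase gene Mmp2 1.99-fold, whereas Timp3, another inhibitor gene, rose 2.33-fold. The antisense gene Syn3 overlaps 21.3% of the Timp3 exon bases.

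Smooth muscle genes did not move as 1 group. Of 23 contractile genes 9 rose, 9 fell and 5 did not pass (10 and 9 adjusted over the list alone). Myh11, the smooth muscle myosin heavy chain, rose from 4008 ± 11.8 to 4819 ± 31.9 CPM, and Acta2, smooth muscle actin, fell from 9871 ± 36.9 to 8037 ± 5.90 CPM, although it is higher by 0.11 with library totals. The pericyte and smooth muscle gene Rgs5 fell 1.91-fold and Des, which encodes desmin, fell 4.55-fold. The list's median was 0.05, its mean -0.14 and its test downward (limma camera adjusted p = 0.0393, but adjusted p = 0.121 with an estimated correlation, and 8.6e-05 to 0.739 over all alternatives), and the call was lost without labelled knockout 1 and turned upward with library totals (median 0.46). Of 18 markers of modulated smooth muscle, cells that have left the contractile state, 13 fell, 2 rose and 3 did not pass, the same counts as adjusted over the list alone. Their median was -0.58 (limma camera adjusted p = 1.36e-42), or -0.17 with library totals (limma camera adjusted p = 5.57e-18). Spp1, which encodes osteopontin, fell 25.2-fold from 355 ± 9.35 to 14.1 ± 1.30 CPM, Col8a1 fell 3.69-fold and the calcification inhibitor gene Mgp 1.78-fold, and Thbs1 is also on this list.

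Proliferation genes were lower in the labelled knockouts. Of 34 cell-cycle genes 31 fell, none rose and 3 did not pass by edgeR, or 33 lower when adjusted over the list alone, with a median log2 fold change of -1.83 (limma camera adjusted p = 4.21e-21), and -1.42 with library totals (limma camera adjusted p = 3.5e-17). DNA topoisomerase gene Top2a fell from 20.9 ± 2.57 to 4.68 ± 0.439 CPM, the proliferation marker gene Mki67 fell 3.81-fold, the cyclin gene Ccna2 4.90-fold and Prc1, needed for cytokinesis, 4.99-fold. Targets of p53 and genes of cell cycle arrest and apoptosis counted 9 lower, 2 higher and 11 not passing of 22 (10 and 2 adjusted over the list alone), with Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases, 2.35-fold lower, Phlda3 at -0.67, Ccng1 at -0.56 and Trp53inp1 at 0.38, of which Ccng1 lost its call with library totals (-0.15, edgeR adjusted p = 0.0894). That list's call was lost (limma camera adjusted p = 0.0211, then adjusted p = 0.109 with an estimated correlation, and 2.97e-05 to 0.306 over all alternatives). Library totals turn its median from -0.21 to 0.20, with 8 higher and 2 lower and no call. Of 25 genes of the unfolded protein response 10 fell, 5 rose and 10 did not pass (11 and 5 adjusted over the list alone). The chaperone gene Hspa5 fell 1.55-fold, Calr by 0.31, the stress factor gene Atf3 2.48-fold and Pdia6 by 0.41, with Calr at 0.10 by library totals, where Pdia6 lost its call at -0.0037 (edgeR adjusted p = 0.954). This call too was lost (limma camera adjusted p = 0.0257, then adjusted p = 0.109 with an estimated correlation, and 0.00104 to 0.766 over all alternatives), and library totals turn its median from -0.12 to 0.29 with 15 higher and 2 lower. Of 30 immediate early and heat shock genes, which dissection itself can induce, 20 fell, 2 rose and 8 did not pass (21 and 3 adjusted over the list alone). Fos fell by 1.32 on the log2 scale, Egr1 1.69-fold, Btg2 2.14-fold and Nr4a1 1.76-fold, and the median was -0.35 (limma camera adjusted p = 2.25e-15). With library totals it was 0.06, with 12 higher and 9 lower, while the call stays downward relative to other genes (limma camera adjusted p = 0.000497).

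Macrophage genes fell. Of 28 macrophage and monocyte markers 22 fell, 1 rose and 5 did not pass (24 and 1 adjusted over the list alone), with a median of -0.93 (limma camera adjusted p = 1.96e-23), and -0.52 with library totals (limma camera adjusted p = 2.7e-12). Lysozyme gene Lyz2 fell from 401 ± 8.18 to 156 ± 0.433 CPM, the complement C1q genes C1qb and C1qa fell 2.21-fold and 1.85-fold, and the leukocyte membrane gene Laptm5 2.34-fold. Of 33 cytokine, chemokine and adhesion genes 15 fell, 7 rose and 11 did not pass (15 and 8 adjusted over the list alone; limma camera adjusted p = 0.000136). Their median was -0.53, or -0.12 with library totals, where 11 were higher and 11 lower and the call stays downward (limma camera adjusted p = 0.000515), and the call was lost at a mean FPKM of at least 5 (7 genes tested, limma camera adjusted p = 0.0512). The adhesion molecule gene Vcam1 fell 2.81-fold, the chemokine gene Ccl9 2.41-fold and the prostaglandin synthase gene Ptgs2 3.17-fold, while Nfkbia, an inhibitor of NF-kappaB, rose 1.79-fold. Of 24 lymphocyte markers 8 rose, 1 fell and 15 did not pass (8 and 2 adjusted over the list alone). The immunoglobulin genes Jchain, Igkc and Iglc2 rose by 1.30, 1.55 and 1.83, and the T cell coreceptor gene Cd8a by 2.38. The 1 that fell, named after its values were seen, was the immunoglobulin M heavy chain gene Ighm at -0.57 (edgeR adjusted p = 0.00736, a call lost with library totals, where it is at -0.16). The list did not pass as a set (limma camera adjusted p = 0.243) except upward at a mean FPKM of at least 1 (6 genes tested, limma camera adjusted p = 0.0385) and without wild type 3 (limma camera adjusted p = 0.0162), which had 1.89 times the mean Igkc level of the other wild type libraries when scaled by library totals. None of 11 neutrophil markers passed edgeR's test, adjusted over all genes or over the list alone, among them S100a9 at 0.60 (edgeR adjusted p = 0.0919), Il1b at -0.53 and Retnlg at 1.01. S100a9 did pass upward in 11 alternatives (adjusted p of 0.000471 to 0.0443). These were all 8 limma fits on FPKM, DESeq2, library totals and the fit without wild type 1. Mmp8 had 13 read pairs in wild type and 3 in the labelled knockouts (ratio 6.16, 95% counting interval 1.69 to 33.7). Although that interval leaves out equal levels, edgeR did not call Mmp8 (adjusted p = 0.183). The list's test stood at a limma camera adjusted p of 0.994, with a mean of -0.16 and a median near 0 that differ in sign.

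Interferon-stimulated genes did not move as a set (limma camera adjusted p = 0.861), with 3 higher, 4 lower and 22 not passing, the same counts of calls as adjusted over the list alone. With library totals 15 were higher and none lower, also without a call as a set (median 0.40, limma camera adjusted p = 0.957). Irf1 rose by 0.45 and Iigp1 by 0.54, and the antiviral genes Oas1a and Ifitm3 fell by 0.91 and 0.20, where Ifitm3 is at 0.21 with library totals. Oas1a loses its call there (-0.51, edgeR adjusted p = 0.0529), and another gene shares 100% of the Oas1a transcript. Of 19 complement genes 9 rose and 8 fell, adjusted over the list alone as well, with a median of 0.18, a mean of -0.08 and no call (limma camera adjusted p = 0.618). With library totals the list was called upward (median 0.59, limma camera adjusted p = 0.00247), as it was by fry and with members of several lists left out. Cfd, which encodes the adipocyte-made complement factor D, rose 1.80-fold and C4b 1.72-fold, against the decrease in macrophage-made C1qb.

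Endothelial genes rose. Of 24 markers 18 rose, 2 fell and 4 did not pass (20 and 2 adjusted over the list alone), with a median of 0.57 (limma camera adjusted p = 1.75e-20). Von Willebrand factor gene Vwf rose from 108 ± 2.94 to 232 ± 6.08 CPM, the diaphragm protein gene Plvap 2.66-fold, the receptor gene Tie1 2.22-fold and the vascular phosphatase gene Ptprb 1.64-fold. White fat markers also rose, 12 of 24 higher, 1 lower and 11 not passing (14 and 3 adjusted over the list alone; limma camera adjusted p = 0.000208), with Cfd again, the fatty acid transporter gene Cd36 at 0.50, the lipid droplet gene Plin4 at 0.35 and the adipokine gene Adipoq at 0.93. Brown fat markers did not pass as a set (limma camera adjusted p = 0.783), with 2 higher, 2 lower and 17 not passing (1 and 2 adjusted over the list alone) and a median of 0.01 beside a mean just below 0. The thyroid hormone deiodinase gene Dio2 rose by 1.06, Cidea rose by 0.62, a call lost in 4 of the 6 fits without 1 library, Pdk4 fell by 0.97 and Prdm16 by 0.35, or 0.06 higher with library totals. Of 23 adventitial fibroblast markers 10 rose, 9 fell and 4 did not pass (11 and 9 adjusted over the list alone). Serpinf1 and Gpx3 rose by 0.55 and 0.58, and Cd248 and Ly6a fell by 0.82 and 0.60. The fibroblast median was 0.11, its mean -0.08 and its test downward without a call (limma camera adjusted p = 0.994), and with library totals it was called upward.

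Some markers of tissues around the aorta differed as well, though none of the 6 lists that follow passed in all alternatives. Fry called the heart muscle, the nerve and glia, and the lymph node and thymus lists upward (fry adjusted p of 0.0103 to 0.0139). Of 22 skeletal muscle genes 3 rose, 6 fell and 13 did not pass (3 and 7 adjusted over the list alone; limma camera adjusted p = 0.994, upward, with a median of -0.94, and a call upward at a mean FPKM of at least 1, where 5 genes were tested, adjusted p = 0.019). The sarcomere gene Tcap rose by 1.78 and the calcium-binding gene Casq1 by 1.09, while the skeletal actin gene Acta1 fell by 4.05 and Myoz1 by 1.56. Of 13 heart muscle genes 2 rose, 1 fell and 10 did not pass, adjusted over the list alone as well (limma camera adjusted p = 0.618), with the troponin gene Tnnt2 higher by 0.61, the atrial myosin gene Myl7 at least 2.47-fold higher from 0 counts, and the ryanodine receptor gene Ryr2 lower by 0.37, a call lost in 3 of the 6 fits without 1 library and at 0.04 with library totals. Tnni3 did not pass, at 1.02, but did in 4 alternatives (DESeq2, library totals, the replicate block and without wild type 3). Nerve and glia markers numbered 4 higher, 4 lower and 11 not passing, adjusted over the list alone as well (limma camera adjusted p = 0.543, a median of 0.14 and a mean of -0.12), with Ncam1, Scn7a and the myelin gene Pmp22 higher by 0.63, 0.87 and 0.51 and the neuronal tubulin gene Tubb3 lower by 1.73. Red cell and platelet transcripts fell in 6 of 12, the others not passing, with 7 lower when adjusted over the list alone (limma camera adjusted p = 0.00509, but adjusted p = 0.0826 with an estimated correlation, and 3.38e-06 to 0.198 over all alternatives). Ppbp fell by 4.92, the globin genes Hbb-bs and Hbb-bt by 0.60 and 0.75, and the platelet factor gene Pf4 by 0.77, and 55.9% of the Hbb-bt transcript matches Hbb-bs. With library totals Hbb-bs, Hbb-bt and Pf4 were at -0.19, -0.34 and -0.36, Pf4 without a call (edgeR adjusted p = 0.0795). Limma on FPKM ended the call of Hbb-bt in 6 of its 8 fits, of Pf4 in 3 and of Hbb-bs in 1. Of 8 mesothelial and epithelial markers 3 fell and 5 did not pass (4 lower adjusted over the list alone). The lung genes Sftpc, Scgb1a1 and Sftpb fell by 5.87, 2.20 and 4.61, and the mesothelial gene Wt1 did not pass at -1.25, except in DESeq2, on counts divided by 4 and without wild type 2. Their list's call was also lost without each wild type library in turn (limma camera adjusted p = 0.0165, then adjusted p = 0.109 with an estimated correlation, and 0.000511 to 0.878 over all alternatives). Of 9 lymph node and thymus genes 4 rose and 5 did not pass (5 higher and 1 lower adjusted over the list alone; limma camera adjusted p = 0.313). The recombinase gene Rag1 had 2 read pairs in wild type and 106 in the labelled knockouts (ratio 37.3, 95% counting interval 10.1 to 312), Dntt 3 and 72 (ratio 16.9, 5.55 to 83.7), Cxcl13 rose by 1.07 and Cd1d1 by 0.77. The calls of Dntt and Cd1d1 were each lost without any 1 of the labelled knockout libraries.

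Clock genes, which follow the time of sampling, differed between the groups. Of 17 tested 11 rose, 4 fell and 2 did not pass, adjusted over the list alone as well, with a median of 0.46 (limma camera adjusted p = 1.43e-05). Tef, Dbp, Per3 and Nr1d2 rose 1.72-fold, 1.72-fold, 2.15-fold and 1.41-fold. Of 26 renin-angiotensin and vasoactive genes 10 rose, 6 fell and 10 did not pass (11 and 7 adjusted over the list alone), with a median of 0.13, a mean of -0.30 and no call (limma camera adjusted p = 0.249). Library totals (median 0.54, limma camera adjusted p = 0.00749), median-of-ratios factors and quantile normalisation on FPKM, and fry did call that list upward. The calcineurin regulator gene Rcan1 fell 2.87-fold and Avpr1a 30.5-fold, while the natriuretic peptide receptor gene Npr3 rose 3.16-fold and Ace, which encodes angiotensin-converting enzyme, 1.33-fold. Redox genes showed 5 higher, 10 lower and 12 not passing of 27 (6 and 10 adjusted over the list alone; limma camera adjusted p = 0.545). Library totals gave 16 higher and 4 lower and moved their median from -0.01 to 0.40, without a call (limma camera adjusted p = 0.207). Fry called the redox list downward (fry adjusted p = 0.0298). The extracellular superoxide dismutase gene Sod3 rose by 0.36, Gpx3 by 0.58 and the NADPH oxidase gene Nox4 by 0.30, and the peroxiredoxin gene Prdx1 fell by 0.40, or was at 0.01 with library totals, and 26.0% of its transcript matches other genes.

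Glycolysis and hypoxia genes did not pass as a set (limma camera adjusted p = 0.618, a median of -0.09 and a mean of 0.06), with 4 higher, 8 lower and 13 not passing (5 and 10 adjusted over the list alone). Library totals gave 17 higher and none lower (median 0.32, limma camera adjusted p = 0.0575). Pfkp rose by 0.58, and Pkm, Eno1 and Pgk1 fell by 0.31, 0.39 and 0.45, of which Pkm, Eno1 and Pgk1 are at 0.09, 0.02 and -0.04 with library totals, the last 2 without a call (edgeR adjusted p = 0.643 and 0.458), and at least 65.5% of each of these 3 transcripts matches other genes. Of 30 nuclear respiratory chain genes 12 fell and 18 did not pass (13 lower adjusted over the list alone; limma camera adjusted p = 0.0195, but adjusted p = 0.121 with an estimated correlation, and 3.31e-05 to 0.375 over all alternatives). The ATP synthase subunit genes Atp5o, Atp5a1, Atp5c1 and Atp5b fell by 0.27, 0.12, 0.20 and 0.13 on the log2 scale, each of them higher with library totals, where the list's median goes from -0.12 to 0.29 with 26 higher and none lower. Antisense genes and a second model overlap 47.9% of the Atp5o exon bases. Among 14 neighbours of Josd2 on chromosome 7, Clec11a, Nr1h2 and Emc10 rose by 0.67, 0.33 and 0.12, Napsa fell by 1.39 and 10 did not pass, adjusted over the list alone as well (limma camera adjusted p = 0.618, a median of 0.02 and a mean of -0.08). The Emc10 call was lost in 4 of the 6 fits without 1 library. Of 28 deubiquitinase and ubiquitin genes 8 rose, 1 fell and 19 did not pass (8 and 2 adjusted over the list alone; limma camera adjusted p = 0.478). Fry called that list upward, as did camera with library totals (median 0.42, limma camera adjusted p = 0.00368). Wwp2, a ubiquitin ligase gene, rose by 0.44 and the deubiquitinase genes Usp22, Otud7b and Usp10 by 0.37, 0.28 and 0.35. Of 3 replication-dependent histone genes H1f2 fell by 0.62, while H2bc4 at -0.22, or 0.19 with library totals, and H4c8 at 0.32 did not pass, against 2 lower adjusted over the list alone. H2bc4 gained a call downward in 7 alternatives (adjusted p of 0.00672 to 0.046), and upward with library totals (edgeR adjusted p = 0.0498) and the 6 limma fits on FPKM scaled to totals. No sex-linked gene passed edgeR's main test, adjusted over all 5 or over all genes (limma camera adjusted p = 0.861, a median of 0.06 and a mean of -0.35), with Ddx3y at 0.17, Kdm5d at 0.22, Eif2s3y at 0.06 and Xist at -2.20 (SE 1.05). With library totals 4 of the 5 passed upward, among them Ddx3y, Kdm5d and Eif2s3y (edgeR adjusted p = 1.93e-05, 0.000277 and 9.13e-05). The 6 limma fits on FPKM scaled to totals also called Ddx3y and Eif2s3y. DESeq2 called Xist downward (adjusted p = 0.0265) and Ddx3y upward. EdgeR called Ddx3y without wild type 1, at a mean FPKM of at least 5 and with library totals once mitochondrial genes and copies were left out.

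**Figure D3:**
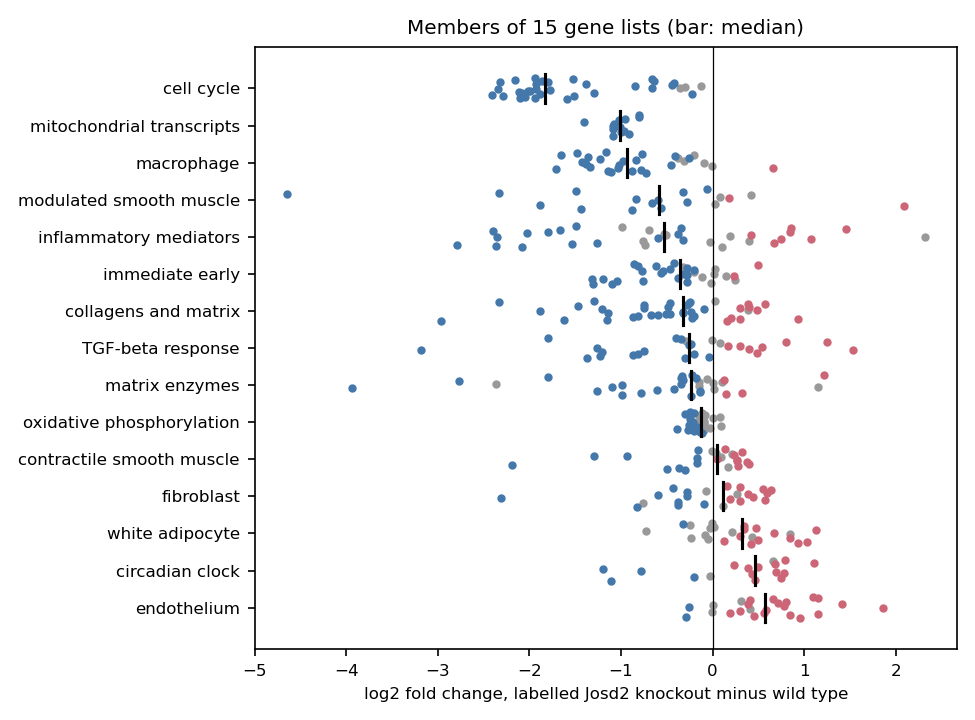
Log2 fold change between the libraries labelled knockout and wild type (horizontal axis, TMM scale) of each tested member of 15 gene lists, with red points for genes that rose, blue for genes that fell, grey for those that did not pass, and a black bar at the list's median. Medians run from -1.83 for the cell cycle to 0.57 for endothelium, and with library totals those of matrix, matrix enzymes, TGF-beta response, immediate early and respiratory chain genes lie above 0.

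Annotation terms of GO and KEGG were tested with camera, and 287 of 3987 passed, 108 higher and 179 lower, none of them with an estimated correlation (adjusted p of 0.401 to 0.466 for the 25 leading terms in each direction). The 3 leading higher terms were lymph vessel development, vascular endothelial growth factor signalling and inhibitors of DNA-binding transcription factors. In lymph vessel development 10 of 12 genes rose, led by Svep1 at 1.88, Tmem204 at 1.22, the lymphatic receptor gene Flt4 at 1.99 and the lymphatic transcription factor gene Prox1 at 3.17 (limma camera adjusted p = 4.31e-10, then adjusted p = 0.418 with an estimated correlation). In the growth factor term 9 of 13 rose, led by Flt1 at 1.07, Vegfd at 1.23, Kdr at 1.86 and Flt4 (limma camera adjusted p = 7.83e-07, then adjusted p = 0.418 with an estimated correlation). The inhibitor term had 9 of 13 higher, led by Id1 at 1.53, Id3 at 0.70 and Id4 at 1.34, which block basic helix-loop-helix factors, and Smad7 (limma camera adjusted p = 3.49e-06, then adjusted p = 0.418 with an estimated correlation). The leading lower terms were NADH dehydrogenase activity and the respirasome, both led by mitochondrially encoded genes, and extracellular matrix binding, where 15 of 28 fell and 9 rose, led by Eln, Sparcl1 at -1.72, Thbs1 and Spp1 (limma camera adjusted p = 8.69e-19, then adjusted p = 0.401 with an estimated correlation). NADH dehydrogenase activity had 9 of 27 lower and none higher (limma camera adjusted p = 8.69e-19, then adjusted p = 0.418 with an estimated correlation), and the respirasome 18 of 62 lower and 1 higher (limma camera adjusted p = 9.68e-17, then adjusted p = 0.401 with an estimated correlation). Further down, the ribosome term, picked after its values were seen, had 74 of 132 genes lower and none higher in edgeR (limma camera adjusted p = 7.13e-08, then adjusted p = 0.418 with an estimated correlation). Its leading members Rplp0 at -0.48, Rpsa at -0.34, Rps3a1 at -0.30 and Rps2 at -0.35 share at least 46.0% of their transcripts with copies, and Rpsa, Rps3a1 and Rps2 change sign with library totals, Rps2 without a call (edgeR adjusted p = 0.075). The term for the MHC class II complex, picked in the same way, had 6 of 11 lower, led by the antigen presentation genes H2-Aa at -0.96, Cd74 at -0.86, H2-Ab1 at -0.86 and H2-Eb1 at -0.93 (limma camera adjusted p = 1.0e-05, then adjusted p = 0.418 with an estimated correlation). The term for the MHC class I complex went the other way, with 8 of 10 genes higher and none lower. Limma camera gave it an adjusted p of 5.13e-06, then 0.418 with an estimated correlation. Its members were not compared with other transcripts.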

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

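Library totals, mitochondrial genes left out, counts divided by 4, robust edgeR and other tissues' genes left out were tests chosen only after the results were seen, and all other alternatives were fixed before the data were examined. Direction and side of the threshold were kept in 4289 of 4573 comparisons of 189 named genes with an alternative, while 92 lost a call, 57 gained one and 135 changed sign. Of 957 such comparisons of lists, 870 kept both, 45 lost a call, 25 gained one and 17 turned the direction of the test.

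Limma on deposited FPKM called 8924 (8436 higher, 488 lower) genes, with a pseudocount of 0.1 8904 (8413 higher, 491 lower), with 0.01 8891 (8401 higher, 490 lower), without trend 8901 (8425 higher, 476 lower), with robust eBayes 8931 (8438 higher, 493 lower) and with library weights 8944 (8452 higher, 492 lower). EdgeR on library totals called 10193 (9425 higher, 768 lower). Between 92.5% and 94.7% of these calls were higher, against 53.4% in the main test. FPKM is itself scaled to library totals, and totals without mitochondrial genes and copies gave 5042 calls, 58.7% higher, so mitochondrial reads account for most of the shift by construction. Fewer genes were called at a mean FPKM of at least 5, 2461 (1306 higher, 1155 lower), where only 4829 were tested, and 1200 (518 higher, 682 lower) at least 2-fold. DESeq2 called 6818, edgeR with DESeq2 factors 4971, without a filter 4265, on counts divided by 4 5353, and limma with median-of-ratios factors 4240 and after quantile normalisation 3866.

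Under the 6 limma settings on FPKM scaled to totals and edgeR on totals, Josd2 stood at -0.097, -0.11 and -0.098 (limma and edgeR adjusted p of 0.0981 to 0.231), and other named genes changed sign. Smad3 was at 0.078, 0.099, 0.10 and 0.073, Smad4 at 0.27, 0.30 and 0.31, Tgfbr1 at 0.26 and 0.28, Acta2 at 0.11. Josd1 was at 0.31, 0.35 and 0.30, Ifitm3 at 0.20 and 0.21, Prdx1 at 0.0094, 0.0096 and 0.0066, Calr at 0.10. Pkm was at 0.093, 0.094 and 0.095, Eno1 at 0.018 and 0.019, Atp5o at 0.14, Atp5a1 at 0.29. Atp5c1 was at 0.21, Atp5b at 0.27 and 0.28, Prdm16 at 0.046, 0.058, 0.060 and 0.045, H2bc4 at 0.18 and 0.19. Rpsa was at 0.069, 0.070 and 0.071, Rps3a1 at 0.11, Rps2 at 0.056, 0.058 and 0.057. Ryr2 was at 0.041 with library totals and mt-Nd5 at 0.15 after quantile normalisation. The contractile list's test turned upward. Its median lay at 0.42, 0.45, 0.46 and 0.083, the lowest after quantile normalisation, against 0.05 in the main test. The respiratory chain's median lay at 0.28, 0.29 and 0.27. With library totals the fibroblast list's test turned upward, with a median of 0.52 against 0.11 in the main test. The median of the unfolded protein response was 0.29 with that scaling. Quantile normalisation ended the calls of the mitochondrial, TGF-beta response, p53 and unfolded protein response lists. It also ended those of mt-Co1, mt-Cytb, mt-Nd2, mt-Nd4, Acta2, Ifitm3, Atp5a1, Atp5b and Cidea, and, with a change of sign, of mt-Nd5. The contractile list lost its call as its test turned from downward to upward, with a median above 0 in both. With that normalisation, genes of equal rank in each library get equal values by construction. Apart from the scaling shift, the cause was not tested.

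Called lists numbered 10 at a mean FPKM of at least 5. Called terms numbered 578 without a filter, 188 at a mean FPKM of at least 1, 67 at 5, 671 with library totals and 0 with an estimated correlation; filters change the number of tested genes.

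Leaving out each library in turn gave 3756 to 4458 changed genes (1966 to 2429 higher, 1790 to 2044 lower), 8 to 10 study genes, Josd2 at -0.54 to -0.48, 17 to 18 lists and 288 to 305 terms. Single libraries decided several calls. Those of Smad3 (without wild type 3, labelled knockout 1 or 2), Ryr2 (wild type 2 or 3, labelled knockout 2), Dntt and Ighv14-4 (any labelled knockout), Ighv1-52 (labelled knockout 2), Cidea (wild type 1 or 3, labelled knockout 1 or 3), Cd1d1 (any except wild type 3) and Emc10 (wild type 2 or any labelled knockout) were lost. Tgfbr1, H2bc4 and Wt1 (without wild type 2), S100a9 and Ddx3y (wild type 1) and Tnni3 (wild type 3) gained one. The mesothelial list lost its call when any 1 wild type library was left out and the contractile list without labelled knockout 1, whereas TGF-beta components gained one without wild type 1 or labelled knockout 1, among 9 alternatives that called them, and lymphocytes without wild type 3, as at a mean FPKM of at least 1.

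Samples of both groups share replicate numbers. Deviations of same-numbered samples correlated at 0.052, -0.0037 and -0.027, with highest values for other numbers of -0.023, 0.051 and 0.034. Not every sample correlated best with its own number, so no pairing was seen. With all values near 0, a weak pairing could not be told from none. With the replicate number as a block, edgeR called 4560 genes (2464 higher, 2096 lower), 9 study genes, 18 lists and 279 terms, with Josd2 at -0.52. Of named genes' calls, the block changed those of Cidea, Cd1d1 and Emc10, which were lost, and Tnni3, which was gained, and a lost call is not a weaker effect. At this depth a fold against a group at 0 counts is a bound set by 12 counts per library. In simulated data 52.9% of 1.5-fold changes were recovered, all of them planted in genes with higher mean counts.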

Other observations

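The lists and Hox genes below, and all tests in this part except the count over splits of the libraries, were chosen only after the results were seen. Of 10 lymphatic endothelial genes 6 rose, 2 fell and 2 did not pass in edgeR, with Prox1, which specifies lymphatic endothelium, rising from 0.952 ± 0.299 to 8.64 ± 0.734 CPM, Mmrn1 from 5.17 ± 0.366 to 27.3 ± 1.38 CPM, and Nts by 3.44 on the log2 scale, while Lyve1 fell by 0.26 and Pdpn by 0.57 (n = 3 each). Thymocyte genes rose in 5 of 8, their summed level going from 3.67 to 12.3 CPM. Lung genes fell in 5 of 8 (20.7 to 3.81 CPM summed), kidney genes in 2 of 6 (20.1 to 1.75 CPM, a sum carried by Aqp2 and Ren1, with 3 of the other 4, each under 1 CPM, pointing up) and seminal vesicle genes in 3 of 4 (3.15 to 0.173 CPM), the rest of these lists not passing. The nuclear gene Nnt appears as a pair of models of the same locus, 1 going from 12.2 ± 6.43 to 45.7 ± 2.06 CPM and the other from 3.79 ± 4.50 CPM to 0 counts. As 47.5% of the first model's exon bases are overlapped, reads may be divided between the models, and their opposite directions are not separate results. The whole wild type level of the second model is smaller than the rise of the first. The cause of that rise was not tested.

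Between the groups 4981 genes, 9 study genes, 18 lists and 287 terms passed. The highest values over the other splits of the 6 libraries were 0 genes, 0 study genes, 9 lists and 9 terms, so 1 of 10 splits, the real one, reached each value. With 10 splits the share cannot fall under 0.05.

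Josd2 transcript was kept at 69.8% of wild type in the libraries labelled knockout. A swap of some but not all libraries between the groups is argued against, since none lay with the other group on the first principal component, where the gap between the groups was 9.42 times the widest range within a group. Reads of a similar or overlapping gene are argued against too, as 0% of the Josd2 exon bases and longest transcript is shared with other genes. An allele that leaves most of the transcript, or animals that kept the gene, may each give a level of 69.8%, and cannot be told apart without counts per exon. An exchange of all libraries stays open too, as the lowest of the 6 was at 66.2% of the wild type mean and no library lacked the transcript to show which group is the knockout.

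Hox genes, which mark position along the body axis, were ordered by that axis. Of 12 anterior genes 4 rose, among them Hoxa4 by 1.55 and Hoxb4 by 0.64, and of 11 posterior genes 8 fell, with Hoxc11 at least 5.08-fold lower and Hoxa13 at 87 read pairs in wild type against 1 (ratio 124, 95% counting interval 21.6 to 4943). Scaling between libraries is argued against, because posterior minus anterior medians came to -2.93 log2, which no common factor gives. Another stretch of the vessel, or other tissue taken along, may differ between the groups, with a Spearman's rho of -0.83 between fold change and paralog number over 31 Hox genes, which are not independent replicates. The prediction, written after values were seen, was that such a difference moves genes of chest and lower-body organs in opposite directions. Stray tissue of an organ could enter either group whatever the stretch, so the organ lists cannot decide on tissue taken along. Of the lower body, seminal vesicle genes fell in 3 of 4 (median -2.62 with genes at 0 counts at their bound). Kidney genes had a median of -0.33, but only 2 of 6 passed, Aqp2 and Ren1. Most of the other 4 pointed up without passing, so the kidney list did not fall as a whole. Lung genes fell while thymocyte genes rose, although both organs lie in the chest. The difference in tissue thus stays open as a hypothesis, and an effect of genotype on these genes was not tested apart from it.

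Cell-cycle and macrophage transcripts were lower and endothelial transcripts higher. Scaling is argued against, as the macrophage median stays at -0.52 and the cell-cycle median at -1.42 with library totals. A lower share of smooth muscle alone would raise both other cell types alike, but their medians lie 1.51 log2 apart. Their SD over genes was 0.516 for endothelium and 0.564 for macrophages. The pattern was chosen for these opposite directions, so this outcome was fixed in advance. It cannot exclude a lower share beside a separate fall of macrophage genes. Gene length and GC content are argued against, with the smallest of the 3 medians still 0.53 from 0 once that trend is removed. A change in the cells themselves or in the tissue sampled, by genotype or by dissection, may be involved, and the Hox order above leaves both open at these medians 1.51 log2 apart.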
